A study of Mus musculus with 8 samples.

How the data were processed

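ATAC-seq libraries were made from tailbuds of embryos at embryonic day 9.5, 4 from wild-type (WT) and 4 from homozygous Danforth's short tail (Sd/Sd) mice of the CD-1 background. Per the labels' protocols, tailbuds were dissected just behind the last somite and snap frozen, and nuclei were isolated in a Triton buffer and treated with a home-made Tn5 enzyme. Per the series' design text, tailbuds of more than 1 mouse were pooled where needed. Which libraries are pools is not given in the sources used here. Groups were taken from the labels. Replicate numbers were not used in the main fit, since the labels do not say that they mark a litter or day.

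Per the submitters' processing notes, the genome build was mm9 and the tools were CASAVA, bcl2fastq 2.17.1.14, BWA 0.7.15-r1140, Picard, SAMtools, MACS2 2.1.1.20160309 and bedtools 2.26.0. Their order, settings and filters, and whether reads were shifted for the Tn5 cut, are not given in the sources used here. The authors deposited, for each library, a whole-number count per region over 1 set of 26620 regions shared by all 8 libraries, on the 19 autosomes, with no normalization. Whether a count is a read, a fragment or a cut site is not stated, so values are called counts. The authors also deposited, for each library, a list of broad peaks called in that library alone, in the layout of MACS2, with a score, a fold enrichment (a ratio), a −log10 p-value and a −log10 q-value per peak, all of them the peak caller's own values. Peaks reached a q of 0.1 at most. Checked against the peak lists, 26610 of the 26620 counted regions (99.96%) had the bounds of merged peaks of q at most 0.05 present in at least 2 libraries. Of 27239 merged intervals that met this rule the others were not counted, for a reason not given in the sources used here. The region set was thus drawn from the libraries that were then compared, and a region open in 1 library only was not counted.

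Differences between the genotypes were tested on the deposited counts with edgeR 4.0.16 (quasi-likelihood F test with robust variance, TMM scaling, two-sided) in R 4.3.3, with genotype as the only term and all 8 libraries. P-values were adjusted by the Benjamini-Hochberg method over all regions, with a threshold of 0.05. The total count over the regions stands for depth, since numbers of sequenced or mapped reads were not used here, and it also depends on the share of a library that lies in peaks. The filter on low counts (filterByExpr) removed 0 regions. TMM factors lay between 0.9887 and 1.006, and the common biological coefficient of variation was 11.5%. CPM are counts scaled by edgeR to the TMM-scaled library total, and log2 values used a prior count of 2. Intervals are 95% intervals of the fitted change and cover counting error and the spread between libraries. The median interval reached 0.33 log2 units (1.26-fold) to each side. Tested on simulated counts for the 26620 regions with 200 changed per simulation, in 5 simulations, the procedure made 550 true and 34 false calls, none in the wrong direction. These counts were drawn independently for each region. The false calls therefore do not measure errors from differences between libraries that neighbouring regions or whole chromosomes share.

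The window from 18 to 21 Mb of chromosome 2 was set from background knowledge of the mutation, and its regions were also adjusted over the list alone. Regions with an unadjusted p under 0.05 between 10 and 30 Mb of chromosome 2 were compared with all others by Fisher's exact test. Total counts, peak numbers and covered lengths per library were compared by exact permutation tests over 70 arrangements, whose smallest two-sided p is 0.0286. Peaks of all libraries were merged at an overlap of at least 1 bp with bedtools 2.31.1, and a merged interval was called genotype-specific with a peak in 4 of 4 libraries of one group and 0 of 4 of the other. Genotype-specific peaks and the distance between profiles were set against all 35 divisions of the libraries into equal groups. Python 3.11.15 and SciPy 1.17.1 were used for these tests.

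Regions were named by a rule: each region with an adjusted p under 0.05 if 30 or fewer passed, those of smallest p up to 10 in each direction where fewer than 20 passed, and each region of the Danforth window with an unadjusted p under 0.05. Alternatives were DESeq2 1.42.0 (Wald test), limma 3.58.1 with voom quality weights or cyclic loess, other scalings and filters, stricter peaks, other windows, a replicate block, and leaving out each library. The tests, alternatives, windows and naming rule were set before the data were examined. Added afterwards were the counts by chromosome and their alternatives, the test of the first principal component, the flanking regions, the correlation of peak number with total count, edgeR without robust variance and, for the linked segment, other tools, a filter and leaving out libraries, and leaving out libraries also for the distances and genotype-specific peaks, and other tools and a filter for the width classes.

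The reference table used for gene names and gene order is of the GRCm38.p6 assembly, not mm9, so no coordinate of it was used, no region was assigned to a gene, and the 12 gene lists set beforehand (hedgehog pathway, notochord and floor plate and others) were not tested. In place of promoter and distal regions, regions were divided at the median width of 874 bp. The X and Y chromosomes were not analysed here.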

Results

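Chromatin accessibility was profiled by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open chromatin, in tailbuds of mouse embryos at embryonic day 9.5. Wild-type (WT) embryos were compared with embryos homozygous for Danforth's short tail (Sd/Sd), a mutation kept on the outbred CD-1 background that truncates the vertebral column and disturbs the kidneys and hindgut. Each genotype had 4 libraries, and tailbuds of more than 1 mouse were pooled where material was short, so the p-values measure the spread between these libraries. The 8 libraries held between 2873918 and 4180434 counts over a shared set of 26620 autosomal regions, with 3190020 ± 287300 counts in WT and 3546690 ± 471300 in Sd/Sd (mean ± SD, n = 4 each), a difference of 1.11-fold that did not exceed the spread between libraries (exact permutation test, two-sided, p = 0.257). The median region received between 76 and 106 counts per library. Any pair of libraries correlated at 0.93 to 0.948 across regions, where regions are not independent replicates, and no pair of one genotype agreed within counting noise, so all 8 were treated as separate samples.

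The first comparison asked whether chromatin around the mutation differs between the genotypes. As background, Danforth's short tail is known to be a retrotransposon insertion upstream of Ptf1a, which encodes a basic helix-loop-helix transcription factor of the embryonic pancreas and neural tube. In the gene order of the mouse reference, the non-coding genes Gm13344 and Ptf1aos precede Ptf1a. Of 29 regions between 18 and 21 Mb of chromosome 2 (mm9), 2 were more accessible in Sd/Sd tailbuds, and they lay 12145 bp apart. The region from 19352448 to 19354135 rose from 29.9 ± 4.46 CPM (counts scaled to the library total) in WT to 51.4 ± 2.35 in Sd/Sd (mean ± SD, n = 4 each), a 1.72-fold increase (log2 fold change 0.78, SE 0.14, 95% interval 0.52 to 1.05). The region from 19366281 to 19367930 rose from 44.2 ± 3.07 to 62.8 ± 4.30 CPM, a 1.42-fold increase (log2 fold change 0.51, SE 0.12, 95% interval 0.28 to 0.74). In both regions, picked from the 29 by p in the same libraries, every Sd/Sd library exceeded every WT library.

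Adjusted over the list alone, the edgeR quasi-likelihood test gave an adjusted p = 5.31e-07 for the region at 19.35 Mb and 0.000316 for the region at 19.37 Mb, while over all 26620 regions the adjusted p was 0.000487 for the former and 0.0966 for the latter. The region at 19.37 Mb therefore passed within the window and not genome-wide, and its Sd/Sd mean includes 1 library at 69.2 CPM against 60.5 to 60.7 CPM in the other 3. The authors' peak calls, made separately in each library, placed a peak on the region at 19.35 Mb in 4 of 4 Sd/Sd and 2 of 4 WT libraries. On the region at 19.37 Mb they placed one in 4 of 4 Sd/Sd and 3 of 4 WT libraries. Where a peak was called at 19.35 Mb, its fold enrichment was 3.03 to 3.32 in WT and 2.71 to 3.38 in Sd/Sd. At 19.37 Mb the ranges were 2.6 to 3.19 and 2.73 to 3.03. The enrichment of called peaks thus overlapped between the genotypes, and peak presence alone does not measure the difference. The other 27 regions of the window had log2 fold changes from -0.24 to 0.37, and the smallest unadjusted p among them was 0.0614. The 5 regions on each side of the pair, from 18919095 to 20213879, had a median log2 fold change of 0.0055, with 5 above and 5 below 0.

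**Figure D1:**
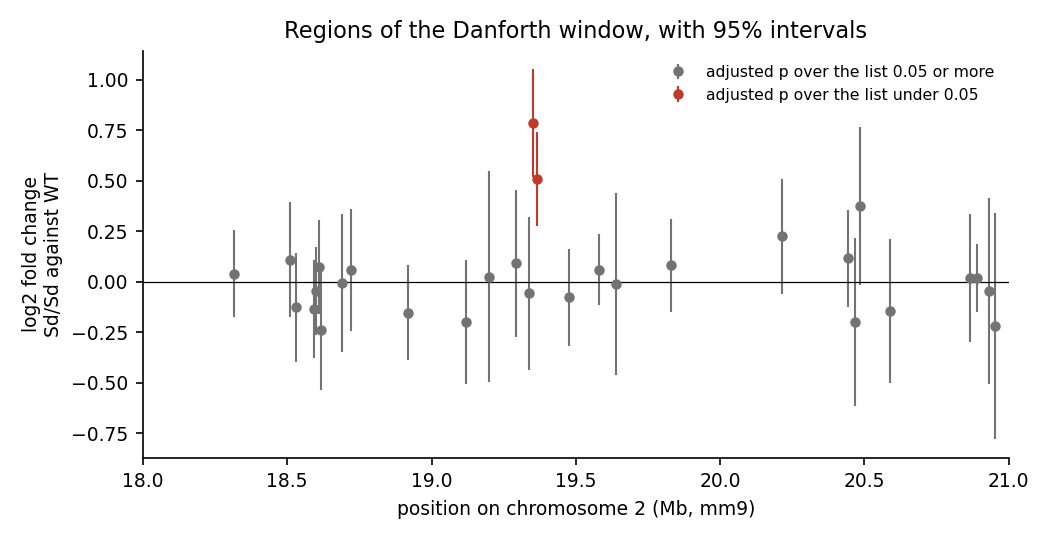
Log2 fold change (Sd/Sd against WT, n = 4 each) with its 95% interval for the 29 regions of chromosome 2 between 18 and 21 Mb (mm9), plotted against position in Mb. The 2 regions in red, at 19.35 and 19.37 Mb, had log2 fold changes of 0.78 and 0.51, and the intervals of the other 27 include 0.

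Across the genome the genotypes differed at few regions. Of 26620 regions, 5 passed an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 2 higher and 3 lower in Sd/Sd, and 3 of these lay on chromosome 2, which holds 9.14% of the regions. Beside the region at 19.35 Mb, a region of chromosome 14 from 42712670 to 42714012 was higher in Sd/Sd, at 115 ± 5.73 CPM against 82.9 ± 8.92 in WT (1.40-fold, log2 fold change 0.48, SE 0.093, adjusted p = 0.00566 in edgeR). A pair of regions on chromosome 2 outside the Danforth window was lower in Sd/Sd. The region from 24617474 to 24619151 fell from 86.4 ± 3.68 to 61.3 ± 6.97 CPM (log2 fold change -0.50, SE 0.10, adjusted p = 0.0179 in edgeR), and the region from 24534540 to 24535183 fell from 26.7 ± 4.46 to 14.6 ± 2.51 CPM (log2 fold change -0.87, SE 0.19, adjusted p = 0.0409 in edgeR). On chromosome 17 the region from 25864251 to 25864762 fell from 26.3 ± 7.22 to 14.2 ± 1.03 CPM (log2 fold change -0.89, SE 0.19, adjusted p = 0.0409 in edgeR). In each of the 5 regions the 4 libraries of one genotype all lay above the 4 of the other, which choice by small p in the same libraries favours.

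**Figure D2:**
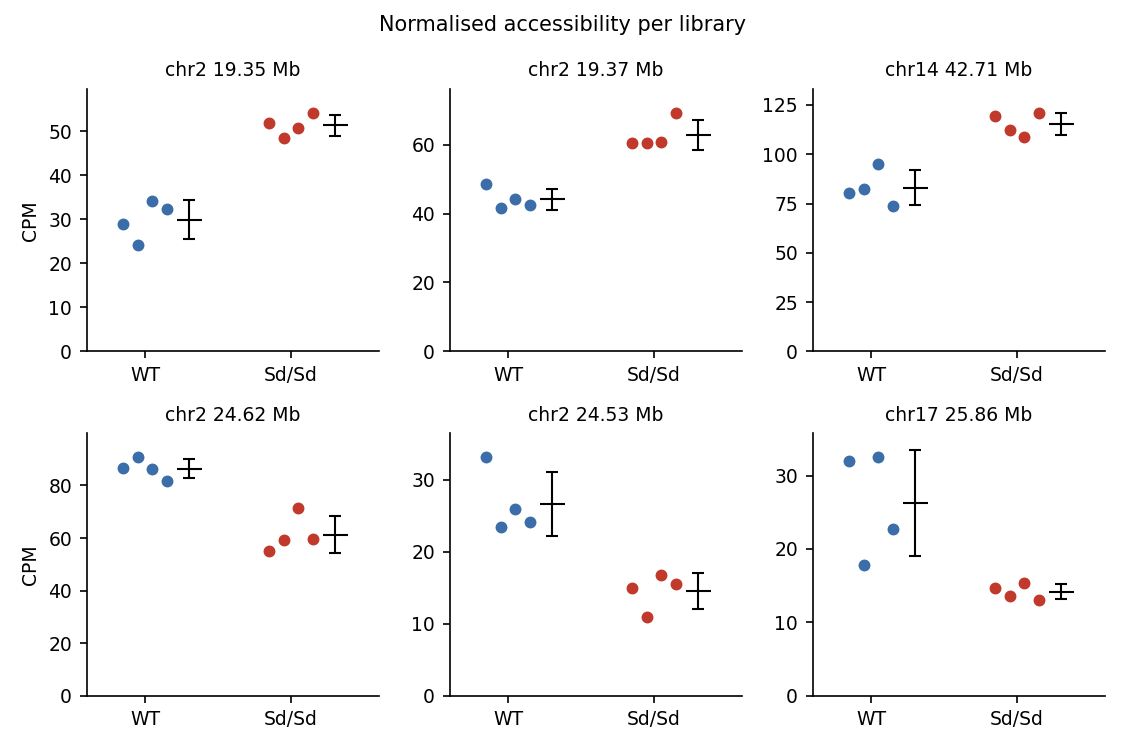
Normalised accessibility (CPM, axes from 0) in each of the 4 WT (blue) and 4 Sd/Sd (red) libraries at the 5 regions with adjusted p under 0.05 and at the region at 19.37 Mb of chromosome 2, with mean and SD in black. The libraries of the 2 genotypes do not overlap in any of the 6 panels, whose regions were chosen by p in these same libraries.

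These calls differed in how far they held when 1 library was left out. The region at 19.35 Mb of chromosome 2 passed in 8 of 8 such fits, with adjusted p from 0.000509 to 0.0306. The region of chromosome 14 passed in 7, its adjusted p reaching 0.0714 without WT replicate 4. Of its 10 flanking regions, 4 had an unadjusted p under 0.05 and the median log2 fold change over the 10 was 0.24. The call at 24.62 Mb of chromosome 2 held in 5 fits and was lost without WT replicate 2, Sd/Sd replicate 1 or Sd/Sd replicate 2. The calls at 24.53 Mb of chromosome 2 and 25.86 Mb of chromosome 17 each held in 3 and were lost in 5 (adjusted p up to 0.392 and 0.364 in edgeR). Both were also lost with DESeq2 (adjusted p = 0.114 and 0.139), with cyclic loess in limma (0.0687 and 0.113) and with voom in limma (0.0665 and 0.107), while the other 3 calls passed with each of these tools. With 1 library left out the log2 fold changes ran from -0.58 to -0.45 at 24.62 Mb, from -0.94 to -0.74 at 24.53 Mb and from -1.03 to -0.78 on chromosome 17. For the Danforth pair they ran from 0.70 to 0.85 at 19.35 Mb and 0.45 to 0.56 at 19.37 Mb. The flanking regions of the chromosome 17 call had a median log2 fold change of -0.18.

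An unadjusted p under 0.05 was reached by 1614 regions (6.06%), 792 higher and 822 lower in Sd/Sd, where 1331 would be reached by chance. For 26107 regions (98.1%) the 95% interval of the change lay within a 2-fold change in either direction, and for 19641 (73.8%) within 1.5-fold, so that changes above 2-fold at most regions were outside what these libraries allow. In simulated counts with the depth and spread of these libraries and 200 changed regions each, the same test recovered 89.6% of 2-fold changes and 43.2% of 1.5-fold changes. The adjusted threshold is stricter where few regions pass, as here, so these shares are likely too high for the data. Differences below 1.5-fold were mostly not detectable at this depth. The libraries of the genotypes did not overlap at 853 regions (3.2%), against 2.86% by chance. The number of calls was small and moved with the fit. DESeq2 gave 3, edgeR without robust variance, an added alternative, gave 15, and limma with cyclic loess, which changes both scaling and test, gave 3. Other scalings within edgeR gave 5. Leaving out 1 library gave from 2 (without Sd/Sd replicate 2) to 19 (without WT replicate 1).

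**Figure D3:**
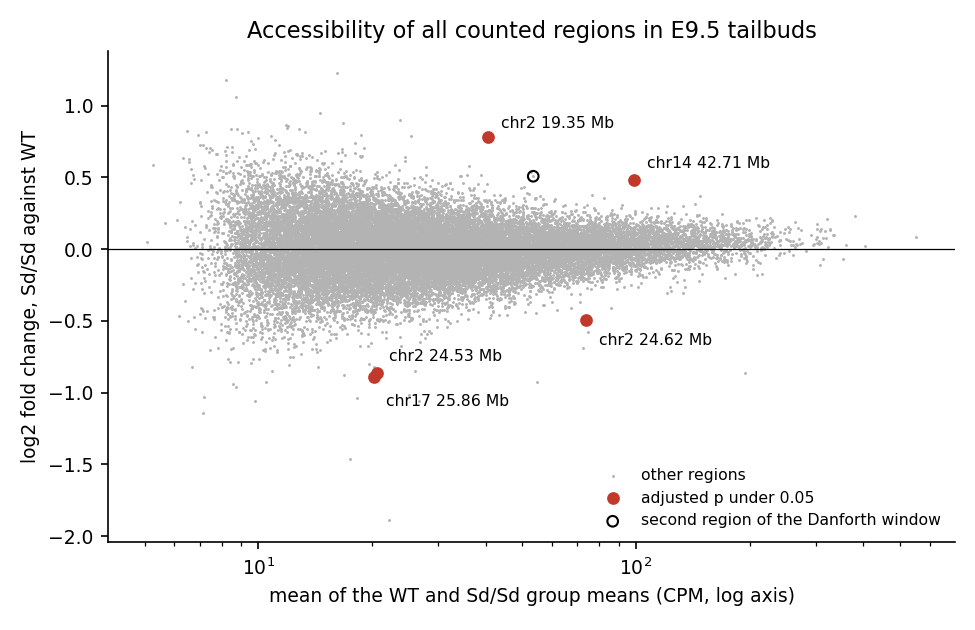
Log2 fold change (Sd/Sd against WT) against the mean of the group means in CPM (log axis) for all 26620 regions, one point per region. Red points are the 5 regions with adjusted p under 0.05, and the open circle is the region at 19.37 Mb of chromosome 2, which passed only over the list of the window.

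The 20 regions named by the rule set beforehand were 10 of smallest p in each direction, and 15 of them did not pass the threshold (adjusted p from 0.0966 to 0.343 in edgeR). Those higher in Sd/Sd had log2 fold changes between 0.38 and 1.18, and those lower between -0.89 and -0.41. Beside the Danforth pair and the call at 42.71 Mb of chromosome 14, the higher regions were at 4.60 and 4.96 Mb of chromosome 14, at 109.35 Mb of chromosome 2, at 4.37 and 103.42 Mb of chromosome 6, at 97.14 Mb of chromosome 4 and at 30.64 Mb of chromosome 1. The change of 1.18, at 4.37 Mb of chromosome 6, rested on 12 to 21 counts per WT library. That region, 103.42 Mb of chromosome 6 and 4.60 Mb of chromosome 14 had a peak in 0 of 4 WT libraries. Sd/Sd libraries with a peak there numbered 2, 2 and 3, so these regions entered the counted set through Sd/Sd peaks alone. At 109.35 Mb of chromosome 2 (109350376 to 109351238) the level was 29.1 ± 3.00 CPM in WT and 43.4 ± 4.02 in Sd/Sd, with an adjusted p of 0.189 in edgeR. Of the lower regions, 4 were on chromosome 17, at 24.49, 25.86, 36.03 and 45.69 Mb, and 3 on chromosome 2, at 24.53, 24.62 and 77.84 Mb. The rest were at 97.05 Mb of chromosome 11, from 17999081 to 18000367 of chromosome 12 and at 104.68 Mb of chromosome 13. At 24.49 Mb of chromosome 17 (24488119 to 24489075) the level was 25.8 ± 3.57 CPM in WT, with a peak in 4 of 4 libraries, and 14.6 ± 2.16 in Sd/Sd, with a peak in 1 of 4 (adjusted p = 0.106 in edgeR). At 16 of the 20 regions the libraries of the genotypes did not overlap, and the 4 exceptions were those at 4.60 and 4.96 Mb of chromosome 14, 77.84 Mb of chromosome 2 and 97.05 Mb of chromosome 11. Choice by small p in the same libraries favours such separation, which 3.2% of all regions showed against 2.86% by chance, so this count is no further evidence.

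Because Sd was bred on an outbred stock, the chromosome segment around the mutation could differ between the genotypes as a whole. All 3 calls on chromosome 2, at 19.35, 24.53 and 24.62 Mb, lie in the segment from 10 to 30 Mb. Between 10 and 30 Mb of chromosome 2, 21 of 233 regions (9.01%) had an unadjusted p under 0.05, against 1593 of 26387 elsewhere (6.04%), an odds ratio of 1.54 (95% interval 0.932 to 2.43) that did not pass the test (Fisher's exact test, two-sided, p = 0.071). Without the Danforth pair the odds ratio was 1.39 (0.821 to 2.24, Fisher's exact p = 0.165). The mean absolute test statistic was 0.868 in the segment and 0.831 elsewhere (permutation test, two-sided, p = 0.36). By Fisher's exact test the odds ratio passed the threshold in a narrower segment from 15 to 25 Mb (1.92, p = 0.0412), with regions counted at an unadjusted p of 0.01 (2.98, p = 0.00465), with DESeq2 (1.94, p = 0.00959) and without WT replicate 4 (1.73, p = 0.01). The 12 regions counted from 15 to 25 Mb and the 9 counted at 0.01 include the Danforth pair and the calls at 24.53 and 24.62 Mb. These alternatives were not run without the pair. It did not pass over the whole of chromosome 2 (1.13, Fisher's exact p = 0.167), with cyclic loess or voom (1.39 and p = 0.167 for each), at regions of a mean count of at least 50 (1.29, p = 0.349) or without any of the other 7 libraries (1.06 to 1.51). Neighbouring regions are not independent, so these p-values are too small by an unknown amount.

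Over all regions a separation of the libraries by genotype was not detectable. Distances between profiles averaged 59.25 between genotypes and 58.66 within them, a difference of 0.581 that was reached by 4 of the 35 divisions of the 8 libraries into equal groups (exact test, p = 0.114). The difference rested on single libraries, since it was -0.388 without Sd/Sd replicate 4, -0.0087 without Sd/Sd replicate 2, 0.930 without WT replicate 1, 1.24 without Sd/Sd replicate 1 and 1.43 without WT replicate 4, and it passed the threshold in none of the 8 such fits (exact test, p from 0.0571 to 0.857). The first principal component took 18.7% of the variance. Its scores were -8.06, -22.1, -19.1 and 3.97 in WT replicates 1 to 4 and -8.14, 14.6, 6.74 and 32.1 in Sd/Sd replicates 1 to 4. The difference between the genotype means did not exceed the spread (exact permutation test, two-sided, p = 0.0857). Regions wider than the median of 874 bp had a median log2 fold change of 0.0014, and narrower ones of -0.00056. The difference between both classes, computed per library, did not differ between the genotypes (exact permutation test, two-sided, p = 0.743), and the mean of Sd/Sd minus that of WT (-0.0018) had the opposite sign to the difference of the fitted medians, so no direction can be given.

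By chromosome, small shifts ran in both directions. Of the regions with an unadjusted p under 0.05, 29 were higher and 99 lower in Sd/Sd on chromosome 11, which holds 1312 regions. The lower count was 57 without WT replicate 1 and 70 without Sd/Sd replicate 4. The median deviation of chromosome 11 from the mean of the libraries was 0.071 in WT replicate 1 and -0.086 in Sd/Sd replicate 4, against -0.0027 to 0.02 in the other 6. The opposite held on chromosome 1, with 93 higher and 41 lower of 2122 regions, and on chromosome 3, with 65 higher and 26 lower of 1791. Chromosome 19 had the largest median log2 fold change in size (-0.0558), with 10 higher and 25 lower of 549 regions. These chromosomes were picked after the counts were seen.

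Peaks called by the authors in each library numbered 21564.5 ± 2617 in WT and 25401 ± 3807 in Sd/Sd (mean ± SD, n = 4 each), a ratio of 1.18 that did not exceed the spread between libraries (exact permutation test, two-sided, p = 0.171). They covered 13.7 ± 1.69 Mb in WT and 16.1 ± 2.63 Mb in Sd/Sd (exact permutation test, p = 0.2). The number of peaks went with the total count over the regions, which rises both with sequencing depth and with the share of the library that lies in peaks. Over the 8 libraries it correlated with that total at a Pearson's r of 0.974 (exact permutation p = 0.000397, adjusted over 2 relations 0.000794). Spearman's rho was 0.929 (exact permutation p = 0.00223, adjusted 0.00446). Without the 2 libraries of most extreme total r was 0.894 (exact permutation p = 0.0222).

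Merging all peaks gave 54165 intervals, of which 11441 had a peak in all 8 libraries and 24519 in 1 library only. Peaks present in 4 of 4 libraries of one genotype and in 0 of 4 of the other numbered 81 for Sd/Sd and 8 for WT. Their sum, 89, was reached by 8 of the 35 divisions of the libraries (exact test, p = 0.229). With the same number of top-ranked peaks taken from each library the genotype-specific peaks numbered 32 for Sd/Sd and 30 for WT, and with peaks of q at most 1e-05 they numbered 16 and 7.

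**Figure D4:**
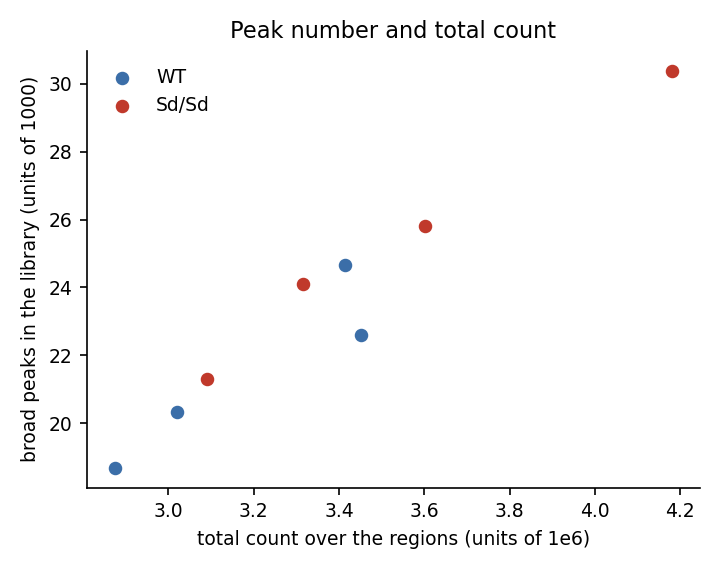
Number of broad peaks, in units of 1000, against the total count over the regions, in units of 1e6, in each of the 4 WT (blue) and 4 Sd/Sd (red) libraries. Peak number rose with the total over the 8 libraries (Pearson's r 0.974), from 18682 peaks at 2873918 counts to 30387 peaks at 4180434 counts.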

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

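The tests in this part were chosen after the results were seen, except that the window around the mutation, the linked segment and the divisions of the libraries had been set before. Of 46 groups of 4 libraries examined, 4 held 1 library far from the other 3, and chance gives about 1 group in 20. At 19.37 Mb of chromosome 2, Sd/Sd replicate 4 had 69.2 CPM against 60.5 to 60.7 in the other Sd/Sd libraries. At 77.84 Mb of chromosome 2 the same library had 23.0 CPM against 10.6 to 11.4. At 4.96 Mb of chromosome 14, Sd/Sd replicate 3 had 11.1 CPM against 24 to 26.1. At 4.60 Mb of chromosome 14, WT replicate 1 had 21.1 CPM against 10.6 to 11.8.

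The rise of the pair at 19.35 and 19.37 Mb of chromosome 2 was weighed first. Of the 35 divisions of the 8 libraries, the real one gave 2 regions past the threshold over the window's list and the highest other gave 1. Thus 1 of 35 reached the real value, the smallest share these divisions can give, which argues against chance assignment of the libraries. Chance is not excluded, since the same divisions were applied to other results without adjustment. A shift of a wider segment is argued against by the flanking regions, whose median log2 fold change was 0.0055 and whose values ran from -0.20 to 0.22. This holds only for a segment that reaches them. The nearest flanking regions end at 19336918 and start at 19474840, so a copy gain or a mapping difference confined between them stays open. A single deviating library is argued against because at least 88.9% of each log2 fold change was kept whichever library was left out. A linked haplotype that alters many regions around the mutation stays open, since the odds ratio without the pair, 1.39, had an interval from 0.821 to 2.24. The mutation itself, as the difference the design names, remains a candidate explanation for the pair, and a sequence variant on the same haplotype in or beside the pair was not tested.

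For the other calls, a segment larger than the region was weighed by the 5 regions on each side. At 42.71 Mb of chromosome 14 the flanks mostly moved with the call, 8 up and 2 down. Their median log2 fold change was 0.242, which only 1.08% of 26449 windows in the genome matched in size. The values ran from -0.413 to 0.668, so the flanks did not move uniformly. A shift of a wider segment, of whatever origin, remains a candidate there. At 24.53 and 24.62 Mb of chromosome 2 the flanks, taken outside the pair, had a median of -0.037, which argues against a shift that extends beyond the pair. A shift confined to the pair and the stretch between its regions was not tested. Both regions lie inside the linked segment, so a linked haplotype stays open for them too. At 25.86 Mb of chromosome 17 the median was -0.178, matched by 5.29% of windows, and a wider shift and a change of the region alone cannot be told apart. The number of calls does not exclude chance: 7 of 35 divisions gave 5 or more and the highest other gave 22, with WT replicate 1 grouped with Sd/Sd replicates 1, 2 and 4. Of those 22, 6 lay at 4 Mb, 3 at 6 Mb, 3 at 7 Mb and 2 at 8 Mb of chromosome 14. The calls of that division thus lay mostly in 1 stretch, where the libraries differ in a way that genotype does not follow.

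The direction of change by chromosome was weighed last. Chromosome medians were as spread in 2 of the 35 divisions (real SD 0.0256, highest other 0.0277), so chance cannot be excluded. The profile of shifts over the 19 chromosomes matched the main axis along which libraries of the same genotype differ, with an absolute Pearson correlation of 0.915 across chromosomes (absolute Spearman 0.884). Permuting the chromosomes gave p = 1e-05 for both, the smallest the permutations can give. This p does not measure the spread between libraries. Per library, the score along that axis (the tilt) was 0.0518 ± 0.0787 in Sd/Sd and -0.0444 ± 0.0353 in WT (mean ± SD, n = 4 each). That difference did not exceed the spread between libraries (exact permutation test, two-sided, p = 0.0571). A bias between libraries is a candidate explanation that the data fit. Sequencing depth stays open, since the tilt correlated with total counts over the regions at r = 0.731 (exact permutation p = 0.0888; Spearman 0.333, p = 0.428) and, without the 2 libraries of extreme total, at -0.0384. Base composition was not tested, for want of the genome sequence, and Sd/Sd replicate 4 had the highest tilt.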

How the results depend on the processing

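Alternatives for edgeR without robust variance, other tools and filters on the linked segment, the width classes and chromosome 11, and leaving out libraries for the segment, chromosome 11, the profile distances and the genotype-specific peaks were chosen after seeing the data. Against 5 differential regions, limma with cyclic loess, which changes scaling and test together, gave 3, DESeq2 gave 3 and edgeR without robust variance gave 15. Leaving out 1 library gave from 2 to 19: 19 without WT replicate 1, 3 without WT replicate 2, 8 without WT replicate 4, 3 without Sd/Sd replicate 1, 2 without Sd/Sd replicate 2, 16 without Sd/Sd replicate 3 and 9 without Sd/Sd replicate 4. Other scalings and filters within edgeR gave 5, voom in limma gave 4 and an adjusted p of 0.10 gave 6. The Danforth window held 2 regions past the threshold over its list under each alternative run. The odds ratio of the linked segment was 1.92 from 15 to 25 Mb, 2.98 at an unadjusted p of 0.01 and 1.94 with DESeq2, all past the threshold, and 1.13 over the whole chromosome, 1.29 at a mean count of at least 50 and 1.39 with loess and with voom, none past it, and from 1.06 to 1.73 with 1 library left out, past it only without WT replicate 4. Genotype-specific peaks, 89 in all, numbered 23 at q of at most 1e-05, and from 156 to 282 with 1 library left out, where fewer libraries must concur. The distance between genotypes minus that within them, 0.581 with all libraries, ran from -0.388 (without Sd/Sd replicate 4) to 1.43, and was -0.0087 without Sd/Sd replicate 2. The difference between wide and narrow regions ran from -0.0021 to 0.0069, turning sign without WT replicate 1 (-0.0021), without Sd/Sd replicate 2 (-0.00065) and with cyclic loess (-0.00071). Lower regions on chromosome 11, 99 in all, numbered 57 (without WT replicate 1) to 119 with 1 library left out. Peak numbers and total counts kept direction and side of the threshold in all alternatives run. Of 339 values of the 20 named regions, 307 kept both, 20 lost and 12 gained significance, and 0 changed sign. All 20 losses fell on the 5 called regions, since for the others keeping the side of the threshold means staying not significant. The calls at 24.53 Mb of chromosome 2 and 25.86 Mb of chromosome 17 each held in 3 of 8 fits with 1 library left out and in 6 of 9 other alternatives. The call at 19.35 Mb of chromosome 2 held in 8 of 8 and 9 of 9. Except where fewer libraries entered, the cause was not tested. With replicate number as a block 23 regions passed, including the 5, and the odds ratio of the segment was 1.49 (not past the threshold). The labels do not say that the numbers pair the libraries. Deviations of same-numbered libraries correlated at 0.004, 0.008, -0.001 and 0.092, and only those of number 4 correlated best with their own. A weak pairing would also give low values, so a shared litter or batch stays open. At this depth changes below 1.5-fold were mostly not detectable. Alternatives without chromosomes X and Y, and those for gene lists, were not run.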

Other observations

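The tests and selections of this part were chosen after the results were seen, except that the linked segment, the divisions of the libraries and the rule naming the 20 regions had been set before. Regions with the largest fitted changes were not the ones that passed the test. A change above 2-fold was fitted at 11 regions, 0 of which passed in edgeR (robust variance), and 6 of which varied among libraries of one genotype far more than other regions of their level (robust prior degrees of freedom under 0.5 of the maximum). At 131327459 to 131327700 of chromosome 6 the fitted log2 fold change of -1.89 (adjusted p = 0.875 in edgeR) came from WT replicate 1, with 108 CPM against 5.56 to 16.8 in the other 7 libraries. Of the 11, 3 lay close together on chromosome 7. From 46585601 to 46586634 the levels were 12.1, 52.5, 50.5 and 28.5 CPM in WT replicates 1 to 4 and 21.1, 23.0, 18.3 and 6.77 in Sd/Sd replicates 1 to 4. From 46455543 to 46456144 they were 15, 51.5, 45.0 and 22.1 CPM in WT and 16.9, 27.5, 16.2 and 6.05 in Sd/Sd, so the same libraries stood high and low at both.

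Such regions of outlying variance numbered 205 of 26620 and lay next to each other on the chromosome: 37 pairs were adjacent, against 1.57 expected and at most 9 in 100000 random draws (permutation p = 1e-05, the smallest the draws can give). They were dense at 89 Mb of chromosome 12 (13 of 33 regions of that megabase), at 176 Mb (6 of 6) and 177 Mb (10 of 49) of chromosome 2, at 46 Mb of chromosome 7 (6 of 13) and at 4 Mb (5 of 9) and 7 Mb (4 of 8) of chromosome 14. The named regions at 4.60 and 4.96 Mb of chromosome 14 lie in one of these stretches. There Sd/Sd replicates 1, 2 and 4 had 27.8, 24.9 and 29.8 CPM at 4.60 Mb and 26.1, 24 and 25.9 CPM at 4.96 Mb, while Sd/Sd replicate 3 had 12.3 and 11.1.

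Chromosome 17 held 4 of the 10 regions of smallest p that were lower in Sd/Sd and none of the 10 that were higher. Over the whole chromosome 51 of 1019 regions were lower at an unadjusted p under 0.05 and 27 were higher, counts that include the named regions and were not tested.

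The number of regions with an unadjusted p under 0.05, 1614, was reached by 8 of the 35 divisions of the libraries, the highest other giving 2426, and the odds ratio of the linked segment, 1.54, by 5 of 35, the highest other giving 1.78, so chance cannot be excluded for either. Signed test statistics of neighbouring regions within 50 kb correlated at 0.176 across regions, which are not independent replicates. Simulated counts gave at most 0.0172, but they were drawn independently for each region, so this comparison says nothing about genotype. Of the 35 divisions, 4 reached the real value and the highest other gave 0.262, so chance cannot be excluded here either.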
